A study of Mus musculus with 2116 samples.

How the data were processed

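Spleen CD4+ T cells of mice with a Foxp3 reporter were sorted by flow cytometry as live, TCR beta positive, CD4 positive cells and encapsulated with inDrops, per the labels' protocols. Libraries were primed with oligo dT, amplified by in vitro transcription and sequenced on a NextSeq500. The deposited table holds UMI counts per gene and cell, as raw whole numbers, per the labels and the values themselves: 23725 genes and 2116 cells, with a largest value of 368. Of the genes, 9003 had no UMI. The submitters' processing notes name TopHat2, SAMtools and the build mm10, with no roles or versions; the annotation, the UMI counter and any filter on cells are not given in the sources used here. Per the labels, the median cell had 53154 mapped reads in Treg and 28462.5 in Tconv, or 31.9 and 19.1 mapped reads per UMI. The UMIs in the table made up 98.4% and 98.1% of the UMI numbers in the labels. No mitochondrial genes with mt- names were in the table.

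Cells were grouped by their titles, and the expansion of the title codes TR and TC to Treg and Tconv was read from the series title. The sort protocol names GFP positive cells for both populations and so does not tell them apart; Foxp3 UMIs were checked against the group labels. The labels give 1 library per group and name no animals, so no p-value, SE or count of changed genes was computed. Cells are not replicates. No column of cells was left out of the table.

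UMIs were summed per library and expressed as counts per 1000000 UMIs in genes (CPM), over 1468203 UMIs in Treg and 2002752 in Tconv. Each sum has an exact Poisson interval, each ratio an exact conditional interval and each share an exact Clopper-Pearson interval, all at 95%. A group with 0 UMIs was set to a floor of 3 counts over the library, which is 2.04 CPM in Treg and 1.50 in Tconv. These intervals assume independent UMIs. Among genes with few UMIs, 22.0% of detections in Treg and 15.5% in Tconv held at least 2 UMIs in the cell, against 3.81% and 3.70% for independent counts, so the intervals are too narrow by an amount not estimated here.

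Gene lists held 288 fixed entries in 22 lists, of which 14 were absent from the table. A list was summarised by the median log2 ratio of its members with at least 20 UMIs in both libraries together, with an interval from 1000 Poisson resamples and its percentile among 10000 random lists matched on size and on mean expression in 20 bins. Shares and scores per cell were computed after thinning each cell to 1000 UMIs without replacement, leaving out shallower cells (78 in Treg and 192 in Tconv). Clustering used cells with at least 500 UMIs, the 1000 most variable of 8733 eligible genes by deviance, log values scaled to 10000 UMIs, 15 components, 15 neighbours and Leiden at a resolution of 0.6. Besides the genes named in the results, ribosomal protein genes and T cell receptor variable genes were left out. Kinases and binding proteins whose symbols begin like those of ribosomal proteins were first counted among them; this was corrected after the clusters had been seen and changed the cluster sizes. A scaled version of the clustering was run first, and the unscaled one was kept after its output had been seen, because the plan named log values. Cells of other types were those with at least 3 UMIs of a B cell, plasma cell, myeloid, erythroid, CD8 or NK, plasmacytoid dendritic or platelet list. Doublets were called with scrublet in scanpy, which marked 9 Treg and 3 Tconv cells; they were kept in the main values and left out in an alternative. Gene positions are from GENCODE annotation of GRCm38, the same assembly as mm10, matched by symbol.

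The groups, the lists, the designs, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the named genes were: the 8 members of the Treg signature and of the Tconv side list with the largest ratio by the interval bound nearest 1; the 12 genes in each direction with the bound farthest from 1 among genes with at least 30 UMIs; the 10 genes per library with the highest Fano factor among those with a mean of at least 0.05 UMIs; and up to 4 members of every other list, with the most abundant member of each list of other cell types. A further part, on effector-like against resting-like clusters, was not applied, because no cluster was given a name. Classes of cells by UMIs of the effector or memory T list were used in its place and were chosen after seeing the data, as were the versions that left out cells with at least 10 UMIs of another type or genes that a list shares with another, and Irf8 without cells of other types. Tigit, Lag3, Tgfb1, Ccr7, Id2 and Izumo1r were named outside the rule, after their values were seen, as were the genes given for the effector classes, for the cells with Cxcr6 UMIs and for the clusters. Some members of the lists are not reported here.

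Alternatives covered the scaling (ribosomal protein genes left out of the total, and TMM factors from edgeR), equal weight per cell, thinning, depth, high-UMI cells, doublets, cells of other types, count minimums and the settings of the clustering. The ratio and Fano factor code was tested on simulated data drawn from the library means. For the ratios these were independent Poisson counts, which the intervals assume, without the clumping of the real UMIs. Their coverage therefore checks the code and not the intervals on these data. In that simulation the intervals covered the true value for 96.3% of 8790 unchanged genes. For changed genes they covered it for 96.0% of 99 at a log2 ratio of 1 and 97% of 100 at 3. Of the genes named by the size rule, 24 of 24 had been changed. Median Fano factors of 0.995 and 2.95 were recovered for genes simulated at 1 and 3. Clustering found 2 of 2 simulated populations, but 3 clusters in 1 simulated population. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scanpy 1.11.5 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Seeds were fixed at 1.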

Results

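CD4+ T cells of the mouse spleen were sorted and their mRNA was counted cell by cell with inDrops, a droplet method in which every captured mRNA molecule receives a unique molecular identifier (UMI). The mice carried a reporter that places green fluorescent protein under the control of Foxp3, the transcription factor that defines regulatory T cells. They were males aged 8 months. One group was labelled as regulatory T cells (Treg, 816 cells) and the other as conventional CD4+ T cells (Tconv, 1300 cells), by title codes read with the series title, which calls the latter Foxp3 negative. The sort protocol names GFP positive cells for both. Each group was 1 library, so no difference between the groups has a replicate check. The Treg library held 1468203 UMIs and the Tconv library 2002752. A Treg cell had a median of 1688.5 UMIs and 708 detected genes, and a Tconv cell 1510.5 UMIs and 686.5 genes. All intervals are 95% intervals and cover counting error only. They are narrower than the true uncertainty, because UMIs were clumped within cells: among 2647 genes measured in both libraries the median Fano factor, the variance of UMIs per cell divided by their mean, was 1.73 in Treg and 1.36 in Tconv, against 1 for independent counts.

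The comparison of the sorted populations asks which transcripts set regulatory apart from conventional CD4+ T cells. Foxp3 (chromosome X, 7573644 to 7595245, plus strand, GRCm38) had 558 UMIs in Treg and 6 in Tconv, or 380 counts per 1000000 UMIs (CPM) in Treg, a log2 ratio of 6.99 (5.86 to 8.44). The fixed list of Treg signature genes was higher in Treg as a group. Of its 23 members with at least 20 UMIs, 22 were at least 2-fold higher in Treg. The exception was Tigit, an inhibitory receptor, at -0.01 (-1.04 to 0.98). The median log2 ratio of the list was 3.62 (3.40 to 4.09), at the 100th percentile of 10000 random lists matched on size and expression.

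The receptors for interleukin 2, the cytokine on which Treg survival depends, were both high in Treg. Il2ra, the high-affinity alpha chain, had a log2 ratio of 6.01 (5.23 to 6.93), and Il2rb, the beta chain, 4.21 (3.77 to 4.69). Lrrc32, which tethers latent TGF-beta to the cell surface, had 130 UMIs in Treg and 0 in Tconv and was at least 59.1-fold higher, against a floor of 3 counts over the library. Ctla4, the receptor that competes with CD28 for its ligands, stood at 5.47 (4.22 to 7.12). Tnfrsf4, the costimulatory receptor OX40, was 25.9-fold higher (16.7 to 42.3). Socs2, a suppressor of cytokine signalling, was at 4.79 (3.71 to 6.13), and Ikzf2, the transcription factor Helios, at 3.84 (3.43 to 4.28).

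**Figure D1:**
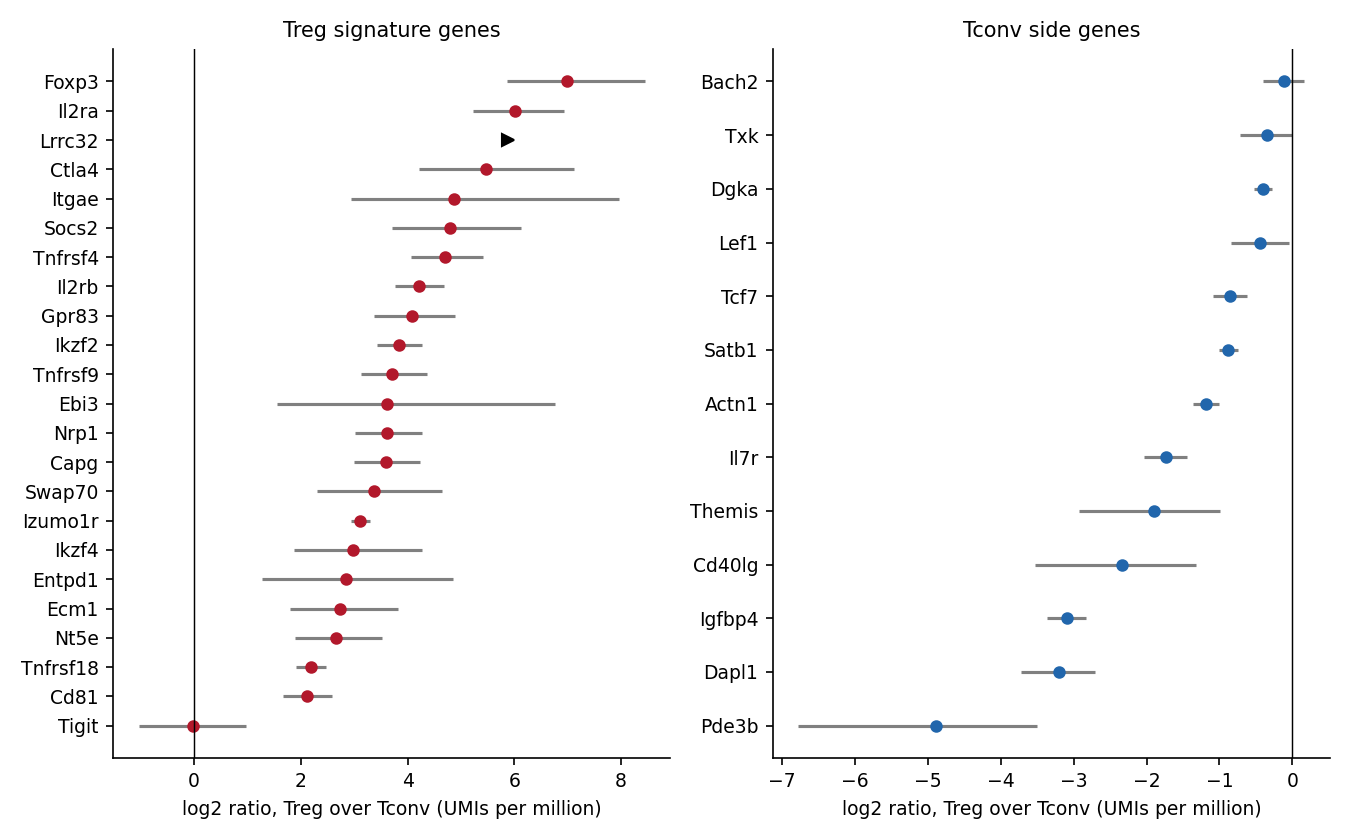
Log2 ratio of CPM, Treg over Tconv, for each measured member of the Treg signature (left) and of the Tconv side list (right). Points are ratios with 95% counting intervals, and the black arrowhead marks Lrrc32, a lower bound because Tconv held 0 UMIs. Tigit lies at -0.01, the other Treg signature genes lie above 0, and the Tconv side genes lie below 0.

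Genes fixed beforehand as higher in conventional cells were lower in Treg. All 13 measured members of this Tconv side list had lower values in Treg, 7 of them at least 2-fold, with a median log2 ratio of -1.18 (-1.34 to -0.99). For 11 of the 13 the interval lay wholly below 0. Pde3b, a phosphodiesterase that degrades cyclic AMP, had the lowest ratio of the list, -4.88 (-6.78 to -3.50), with 2.72 CPM in Treg and 80.4 in Tconv. Igfbp4, an insulin-like growth factor binding protein, stood at -3.10 (-3.37 to -2.84) and Dapl1 at -3.20 (-3.73 to -2.70). Il7r, the interleukin 7 receptor of resting T cells, was at -1.74 (-2.04 to -1.45). Cd40lg, with which helper cells activate B cells, was at -2.34 (-3.53 to -1.32). Actn1 stood at -1.18, Themis, a regulator of thymocyte selection, at -1.90 (-2.93 to -0.99) and Satb1, a chromatin organiser, at -0.88 (-1.01 to -0.75). The resting T list, which shares 9 genes with the Tconv side list, had a median of -0.40 (-0.64 to -0.29), at the 0th percentile of its random lists. Ccr7, the receptor that guides T cells into lymphoid tissue, stood at -1.11 (-1.29 to -0.93).

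Suppression mediators, TNF receptor genes, T cell receptor response genes and effector genes were each higher in Treg as groups, at the 100th percentile of their random lists. The suppression mediators had a median log2 ratio of 3.23 (2.45 to 3.97) over 10 measured members, of which 8 were at least 2-fold higher. This list shares 7 fixed genes with the Treg signature. Among the genes it does not share, Gzmb, the cytotoxic protease granzyme B, had 33 UMIs in Treg and 0 in Tconv, a log2 ratio of at least 3.91, and Fgl2, a secreted inhibitor of T cell responses, had 30 against 2, a log2 ratio of 4.35 (2.38 to 7.47). The Gzmb UMIs came from 8 cells, 1 of which held 13. Lag3, an inhibitory receptor, was at 1.45 (0.14 to 2.88), and Tgfb1, the cytokine TGF-beta 1, had 26 UMIs in each library, a log2 ratio of 0.45 (-0.39 to 1.29). The TNF receptor and NF-kB list had a median of 1.15 (0.92 to 1.43). It shares 3 genes with the Treg signature, Tnfrsf4, Tnfrsf9 and Tnfrsf18, and without them its median was 0.89 (0.77 to 1.20) over 9 members. Its leading members were receptors: Tnfrsf4, Tnfrsf9 (4-1BB) at 3.72 (3.12 to 4.37), Tnfrsf18 (GITR) at 2.18 (1.90 to 2.47) and Tnfrsf1b (TNF receptor 2) at 2.21 (1.79 to 2.65). The TCR response list had a median of 1.14 (0.92 to 1.31) and all 12 measured members were higher in Treg. Cd83, an activation marker, stood at 4.17 (2.98 to 5.66), and the transcription factors Irf4 and Irf8 at 2.26 (1.21 to 3.43) and 1.79 (1.22 to 2.40). The 35 Irf4 UMIs in Treg came from 14 cells, 1 of which held 10. Irf8 is also a gene of plasmacytoid dendritic cells and stands in that list, and 1 cell held 17 of its 89 UMIs in Treg. Without cells that held markers of other types 22 UMIs were left in Treg and 10 in Tconv, a log2 ratio of 1.70 (0.56 to 2.94). Irf8 UMIs count toward that filter, so this ratio does not show whether the difference lies in T cells. Dusp2, a phosphatase of MAP kinases, was at 1.13 (0.96 to 1.30).

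The effector or memory T list had a median log2 ratio of 0.87 (0.65 to 1.07), at the 100th percentile, with 8 of 21 members at least 2-fold higher in Treg. It shares 0 genes with the Treg signature. The calcium-binding proteins S100a4 and S100a6 were 7.60-fold (5.68 to 10.4) and 6.42-fold (5.41 to 7.65) higher in Treg. Ahnak, a large scaffold protein, had a log2 ratio of 1.96 (1.65 to 2.27) and Itgb1, the integrin beta-1 chain, stood at 1.69 (1.46 to 1.92). Id2, a transcriptional regulator of effector cells, went the other way at -1.41 (-1.81 to -1.03). Markers of other cell types were also seen in more cells of the Treg library: 10.4% of its cells (8.41 to 12.7) held at least 3 UMIs of such a list, against 3.62% in Tconv (2.67 to 4.78). In thinned cells the shares were 5.56% and 2.35%, and at a minimum of 10 UMIs 2.57% (1.60 to 3.91) and 1.23% (0.71 to 1.99), with overlapping intervals. The plasmacytoid dendritic list gave the most such Treg cells, 33. Without those cells the median of the effector list was 1.09, that of the TCR response list 1.06, that of the TNF receptor list 1.20 and that of the suppression mediators 3.39. The suppression median was 2.55 with each cell weighted equally, 2.70 in thinned cells and 2.68 without cells above 2 times the median UMIs.

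**Figure D2:**
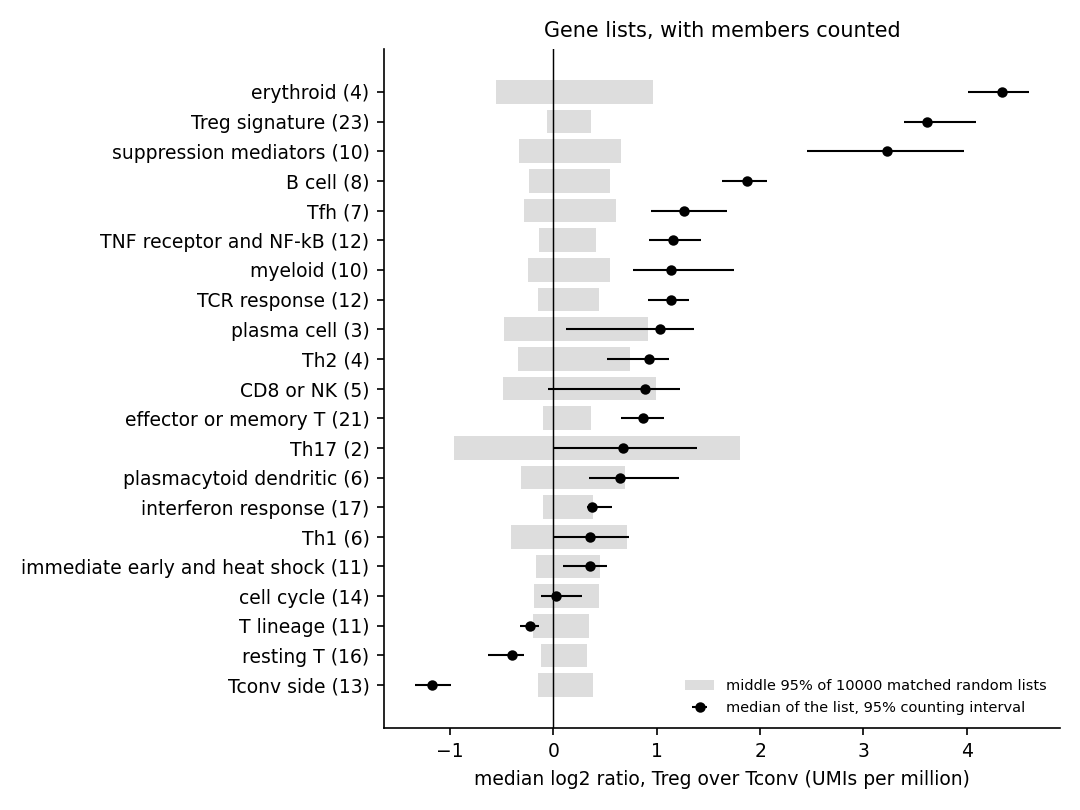
Median log2 ratio of CPM, Treg over Tconv, of each fixed gene list with measured members, whose number is in brackets. Black points are medians with 95% counting intervals, and grey bars span the middle 95% of 10000 matched random lists. The Treg signature lies at 3.62 and the Tconv side list at -1.18, both outside their grey bars.

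Named by size from all genes with at least 30 UMIs, the 12 genes farthest above 1 in Treg were Foxp3, Hba-a2, Lrrc32, Il2ra, Rgs1, Ctla4, C1qa, Tnfrsf4, Hbb-bs, Hbb-bt, Il2rb and Coro2a. Rgs1, a regulator of G-protein signalling, had 225 UMIs against 4, a log2 ratio of 6.26, and Coro2a, a coronin of the actin cytoskeleton, had 10 UMIs in Tconv and a log2 ratio of 4.63. The hemoglobin genes and C1qa, a complement component of macrophages, came almost entirely from single cells: 1 Treg cell held 93.2% of the UMIs of Hba-a2, 97.8% of those of Hbb-bs and all 44 of Hbb-bt, and another held 42 of the 48 of C1qa. Reads of the near-identical hemoglobin copies may also be split between them, which leaves their separate values uncertain. The 12 genes farthest below 1 were Jchain, Cxcr6, Pdlim4, Pde3b, Arhgap29, Igfbp4, Dapl1, Vipr1, Lypd6b, Sgk1, Tgfbr3 and Nme4. Jchain, the joining chain of secreted immunoglobulins, had 0 UMIs in Treg, and 1 cell held almost all of its UMIs in Tconv. Pdlim4 had 2.72 CPM in Treg and 83.4 in Tconv, a log2 ratio of -4.94. Vipr1, a receptor for vasoactive intestinal peptide, was at -3.37, Sgk1, a serum- and glucocorticoid-regulated kinase, at -3.10 and Tgfbr3, the TGF-beta co-receptor betaglycan, at -3.12. Cxcr6, a chemokine receptor, had 0 UMIs in Treg and 61 in Tconv, at least 14.9-fold lower in Treg. Without cells that held markers of other types 30 of the Cxcr6 UMIs were left, and the bound was a log2 ratio of -2.76. Arhgap29 had 0 and 50, at least 12.2-fold lower. Lypd6b and Nme4 each had 1 UMI in Treg, with log2 ratios of -5.01 (-10.3 to -2.46) and -4.94 (-10.3 to -2.39).

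Ribosomal protein genes were lower in Treg. They took 26.1% of UMIs in Treg and 32.6% in Tconv, and 74 of 86 measured genes were lower, with a median log2 ratio of -0.31. Because these abundant genes fill part of the total, the median of all 8988 genes with at least 20 UMIs lay at 0.14 above 0 on the log2 scale. It was 0.01 without ribosomal protein genes in the total and 0.00 with TMM factors. The percentiles among matched random lists do not carry this shift, since the random lists share it.

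Foxp3 and the signature were then read in single cells. With every cell thinned to 1000 UMIs, 25.5% of Treg cells (22.4 to 28.8, exact binomial) held a Foxp3 UMI. In Tconv the share was 0.271% (0.0559 to 0.789). As Tconv was a separate library, its share does not measure free Foxp3 RNA in the Treg library. Of 816 Treg cells 738 were deep enough for thinning, and of 1300 Tconv cells 1108. Unthinned, the shares were 36.4% and 0.462%. Izumo1r, the folate receptor 4 of Treg cells, was seen in 49.9% of thinned Treg cells (46.2 to 53.5) and 8.30% of Tconv cells (6.75 to 10.1), and in 55.8% and 10.7% unthinned. Over the whole Treg signature the median cell had 4 UMIs in Treg and 0 in Tconv. Of the Treg cells, 12.7% (10.4 to 15.4) had no more signature UMIs than the median Tconv cell, that is, none. Of the Tconv cells, 0.993% (0.497 to 1.77) lay above the Treg median. A randomly drawn Treg cell lay above a randomly drawn Tconv cell with a probability of 88.9%, ties counted equally to each side. These shares depend on depth: thinned to 500 UMIs, 16.96% of Treg cells held a Foxp3 UMI and 25.8% had no more signature UMIs than the median Tconv cell.

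**Figure D3:**
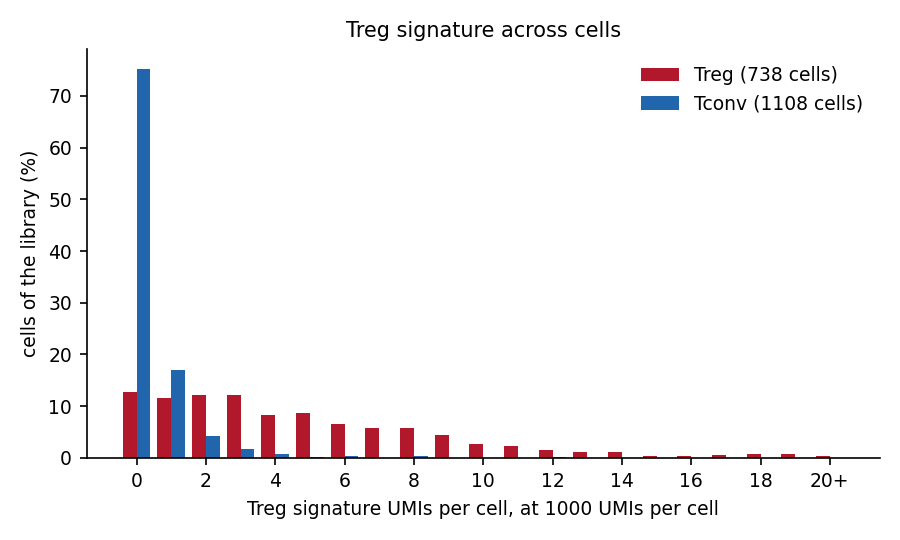
Percentage of cells of each library (vertical axis) with a given number of Treg signature UMIs (horizontal axis), every cell thinned to 1000 UMIs. Red bars are 738 Treg cells and blue bars 1108 Tconv cells. Tconv cells peak at 0 UMIs, where 12.7% of Treg cells also lie.

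Joint clustering asked whether the signature differed within the Treg library. The Treg signature, the Tconv side list and 1034 genes that differed 2-fold between libraries were left out, so that they did not define the clusters. The 2090 cells fell into 4 clusters. Cluster 0 held 23.1% of Treg cells (20.2 to 26.2) and 54.2% of Tconv cells (51.4 to 56.9), cluster 1 held 45.4% and 18.1%, cluster 2 held 16.3% and 23.6%, and cluster 3 held 15.2% and 4.17%. Within the Treg library the signature stood at 4172, 4586, 3611 and 6398 CPM in clusters 0 to 3. Cluster 3 was 1.77-fold (1.61 to 1.95) above cluster 2. Without cells that held markers of other types, the ratio of the highest to the lowest cluster was 1.49. The size of this ratio depended on the clustering: it was 5.41 with all variable genes, which let signature genes define the clusters, 2.45 with scaled genes, 2.20 at a resolution of 1.0 and 1.44 at 0.3. Treg cells were above Tconv cells within every cluster, by 12.6-fold (11.2 to 14.1), 10.01-fold (8.61 to 11.7), 11.7-fold (9.46 to 14.6) and 5.44-fold (4.65 to 6.41). In Tconv cells the signature was also higher in cluster 3, at 1175 CPM against at most 458 in the others.

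No cluster was given a name from the fixed markers. Cluster 3 was led by Jchain and by the macrophage genes Cd5l, Lyz1, Csf1r and C1qa, and 5.71% of its cells held at least 3 UMIs of the myeloid list, 9.14% of the plasmacytoid dendritic, 5.14% of the B cell, 4.57% of the plasma cell and 2.86% of the CD8 or NK list. In the other clusters each of these shares was at most 2.35%. As above, a cell at 3 UMIs of a list need not be of that type. Treg cells of cluster 3 held the effector or memory T list at 8202 CPM, against at most 3019 in the other clusters. They held the resting T list at 1885, against at least 3875. In Tconv these were 4554 against at most 2216, and 2928 against at least 5840. The T lineage list stood there at 5637 CPM in Treg and 5054 in Tconv, against 5302 and 5796 in the whole libraries. Genes of these lists that were not left out could define the clusters. The cells of cluster 3 were deep, with a median of 2515 UMIs, and those of cluster 2 shallow, with 1048. The clusters changed with the settings, from 3 to 9 in number, and the same procedure split a simulated uniform population into 3 clusters. Their number is therefore no count of cell types, and cluster shares that differ between the libraries can reflect the libraries.

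Variation between cells was described gene by gene within each library. By Fano factor at 1000 UMIs per cell, the 10 most variable genes in Treg were Hba-a2, Lyz1, H2-Eb1, Cd79a, H2-Aa, Cd74, S100a6, Myc, Bpnt1 and Itgb1. In Tconv they were Jchain, Lyz1, S100a6, Itgb1, Secisbp2l, Actb, Txndc9, Nfx1, Pcna and Dusp2. S100a6 had a Fano factor of 6.79 in Treg and 4.18 in Tconv, Itgb1 4.92 and 3.57, and Myc, a driver of cell growth, 6.37 and 2.30. Many leading genes belonged to a few cells of other types: 1 cell held 92.3% of the thinned Hba-a2 UMIs in Treg and 1 cell 98.3% of the Jchain UMIs in Tconv. Without cells that held markers of other types, 4 of the 10 Treg genes and 7 of the 10 Tconv genes stayed in the list, and Myc led in Treg at 6.66.

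Genes of B cells, which the sort was meant to exclude, were higher in Treg. The list had a median log2 ratio of 1.88 (1.63 to 2.07), at the 100th percentile. Without cells that held markers of other types this median was 0.73. Of the cells, 2.70% in Treg (1.70 to 4.05) against 0.769% in Tconv (0.369 to 1.41) held at least 3 of its UMIs. Cd74, the invariant chain of antigen presentation, was its most abundant gene, with 190 against 55.9 CPM. H2-Ab1, a class II antigen-presenting chain, stood at 2.92 (2.11 to 3.82) and Cd79a, part of the B cell receptor, at 2.05 (1.58 to 2.55). The myeloid list had a median of 1.14 (0.77 to 1.75), led in abundance by Lyz1, the plasmacytoid dendritic list 0.65 (0.34 to 1.22), led by Ly6c2, and the CD8 or NK list 0.89 (-0.05 to 1.23), led by Cd8b1. The myeloid sign rested on few cells: the median was -0.43 without cells above 2 times the median UMIs and -0.12 without cells with at least 10 UMIs of another type. The CD8 or NK median was -0.20 in thinned cells, and the plasmacytoid dendritic median 0.057 without cells that held markers of other types. Where cells are left out by UMIs of these same lists, B cell and myeloid included, a fall of the median is partly built in. The CD8 or NK and plasmacytoid dendritic lists lay within the middle 95% of their random lists, at the 95.9th and 96.5th percentile. Lyz1 and Ly6c2 have close copies that may share their reads. In the plasma cell list Xbp1, a secretory transcription factor, stood at 1.13 (0.69 to 1.59), Mzb1 at 1.03 and Jchain at least 90.9-fold lower. The list median was 1.03 (0.13 to 1.36) over these 3 members, but -0.42 with members of at least 5 UMIs and -2.69 with members of at least 100. The erythroid median of 4.34 came from the single hemoglobin-rich cell. Platelet genes had 16 UMIs in Treg and 4 in Tconv, with no member at 20 UMIs. Cells with at least 10 UMIs of another type numbered 21 in Treg and 16 in Tconv. In them the T lineage list stood at 991 and 1007 CPM, against 5446 and 5883 in the other cells.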

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

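The versions without cells that held at least 10 UMIs of another type, with genes scaled to unit variance, with effector classes and without genes that a list shares with another were chosen only after the results had been seen, as was the decision to treat every list, and the probability that a Treg cell lay above a Tconv cell, as a main result; the tolerances behind "moved" for probabilities (0.02), Fano factors (0.05), cluster agreement (0.9) and variable genes (7 of 10) were fixed in the code. No paired analysis was possible because each group was 1 library and its results come from no test. The log2 ratio of Foxp3 stayed between 6.79 and 7.15 in every alternative, the median of the Treg signature between 3.48 and 4.08 and that of the effector list between 0.73 and 1.09. Among the recomputed ratios of named genes, 19 moved outside the main interval in the same direction, 6 changed sign and the others stayed within it. The 6 were ratios of C1qa, Hbb-bs and Jchain, where a library with 0 UMIs was set to the floor of 3 counts. Their signs come from that floor and not from the counts. No value was obtained for Th17 members with at least 100 UMIs, because no member was left. Where no reason is given, the cause was not tested.

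Without ribosomal protein genes in the total, the medians were 0.24 for the interferon response, -0.10 for the cell cycle and -0.36 for the T lineage; with TMM factors they were 0.24, -0.11 and -0.37. The cell cycle sign thus depended on the scaling. With each cell weighted equally, the B cell median was 2.29 and the erythroid 3.66. In cells thinned to 1000 UMIs the myeloid median was 1.83, the erythroid 3.07 and the CD8 or NK -0.20. Without cells above 2 times the median UMIs, the myeloid median was -0.43 and Jchain was at 0.12. The cell rich in Jchain had been left out, and the 0 Jchain UMIs in Treg were set to the floor of 3 counts. The positive sign comes from this floor and does not mean that Jchain was higher in Treg. Without cells with markers of other types, medians were 1.09 for the effector, 0.73 for the B cell, 0.15 for the myeloid, 0.057 for the plasmacytoid dendritic and -0.85 for the erythroid list. Cells were left out by UMIs of the lists of other types, so moves of those lists are partly built in. The ratios of C1qa, Hbb-bs and Jchain were -1.02, -1.02 and 0.15. C1qa and Hbb-bs each had 1 UMI in Treg and 0 in Tconv, and Jchain had 0 and 4. These signs come from the floor of 3 counts, as no count turned. Without cells with at least 10 UMIs of another type, medians were 0.97 for B cell, 0.054 for plasma cell, -0.12 for myeloid and -1.12 for erythroid. Hbb-bs stood at -1.12 and Jchain at 0.054, the same values as the erythroid and plasma cell medians. Hbb-bs had 0 UMIs in Tconv and Jchain 0 in Treg, so these values reflect the floor and show no reversal. With members of at least 5 UMIs, Th17 was 1.83, cell cycle -0.13 and plasma cell -0.42. With members of at least 100 UMIs, Tconv side was -0.88, suppression mediators 5.68, TCR response 0.90, cell cycle -0.051, plasma cell -2.69, myeloid 0.50 and erythroid 5.92, since fewer members were left. Without genes of the Treg signature the TNF receptor median was 0.89, and without those of the plasmacytoid dendritic list the TCR response median was 1.13.

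Shares per cell moved with depth, which sets how often a transcript is seen. Unthinned, 36.4% of Treg cells held a Foxp3 UMI and 9.80% had no more signature UMIs than the median Tconv cell. At 500 UMIs these were 16.96% and 25.8%, with a probability of 82.8% that a Treg cell lay above a Tconv cell, and at 1500 UMIs 34.04% and 9.42%. The median Fano factor was 1.42 in Treg and 1.21 in Tconv at 500 UMIs, and 1.91 and 1.45 at 1500. Cells with markers of other types were 5.56% in Treg and 2.35% in Tconv when thinned, and 18.3% and 9.69% at a minimum of 2 UMIs. The upper effector class held 11.1% of Tconv cells at 1500 UMIs. The ratio of the highest to the lowest cluster in the Treg signature was 1.44 at a resolution of 0.3, 2.20 at 1.0 (with 9 clusters), 5.41 with all variable genes, 1.49 without other cell types and 2.45 with scaled genes. Agreement with the main clusters (adjusted Rand index) was 0.987 with another seed but 0.157 to 0.641 in the other alternatives.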

Other observations

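The tests of effector classes, of Klrd1, of the cells with the most Cxcr6 UMIs, of the innate-like list without Il2rb, of clumped counts and of the mapped-read window were chosen only after the results had been seen; the value of the clumped-count test had been estimated before its prediction was written, and an explanation was taken as argued against where the interval lay outside all that it allowed, a rule also set after the values had been seen. Of the T helper lists, the Tfh list had a median log2 ratio of 1.27 (0.94 to 1.68), with Cd200, an inhibitory ligand, at 2.26, the costimulator Icos at 1.54, the follicle-homing receptor Cxcr5 at 1.65 and Sh2d1a, the adaptor SAP, at 1.05. The Th2 list stood at 0.92 (0.52 to 1.11), with the transcription factor Gata3 at 1.10 (0.85 to 1.36) and Il4ra at 0.87. The Th1 list stood at 0.35 (-0.0036 to 0.73), with Ccl5 at 1.14 and Cxcr6 lower in Treg, and the Th17 list at 0.67 (-0.01 to 1.39) over only 2 members, Il1r1 and Tmem176b. Among matched random lists Tfh lay at the 99.98th percentile, Th2 at the 98.98th, Th1 at the 77.5th and Th17 at the 79.7th; the last 2 lay within the middle 95%, and no test compared the lists. Interferon response genes had a median of 0.38 (0.32 to 0.57), with Ifi27l2a at 1.18, Isg20 at 1.28 and Igtp at 0.59, at the 97.3rd percentile. Immediate early and heat shock genes stood at 0.35 (0.09 to 0.52), with the phosphatase Dusp1 at 1.88, Junb at 0.68, Jund at 0.51 and Zfp36 at 0.50, at the 91.9th percentile. Both lists lay within the middle 95% of their random lists, as did the cell cycle list at the 27.2nd percentile. Cell cycle genes stood at 0.03 (-0.12 to 0.28), a sign that turned with the scaling, with H2afz at 1.11, Rrm2 at 1.72, Stmn1 at -1.37 and Pcna at -0.46. T lineage genes stood at -0.23 (-0.32 to -0.14), with Cd2 at 0.91, Cd4 at -0.49 and Thy1 at -0.37, at the 1.36th percentile.

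Within the Treg library, cells rich in effector transcripts carried more of the Treg signature. Cells thinned to 1000 UMIs, without those of other types, were classed by UMIs of the effector or memory T list, more than 3 for the upper and at most 1 for the lower class. The classes are ranges of a score: 320 and 742 of 1727 cells lay at those limits or 1 UMI above. The signature was 1.46-fold (1.34 to 1.59) higher in upper than in lower Treg cells. Tnfrsf1b was 4.42-fold (2.41 to 8.64) higher, Itgae, an integrin of tissue-resident T cells, 8.33-fold (1.91 to 75.5), Ctla4 3.36-fold (1.90 to 6.23), Capg 3.10-fold and Nrp1 2.47-fold. Foxp3 was 1.09-fold (0.80 to 1.48) and Il2ra 0.775-fold (0.567 to 1.06). Of resting and TCR response genes, Lef1 and Nr4a1 were lower, at 0.229-fold and 0.238-fold, but Il7r and Cd69 higher, at 2.84-fold (1.44 to 5.91) and 2.10-fold (1.12 to 4.06). In Tconv the signature was 2.95-fold (2.33 to 3.73) higher in the upper class, with Izumo1r at 3.27-fold and Ikzf2, 17 against 3 UMIs, at 18.5-fold (5.35 to 98.6). The Treg to Tconv ratio of the signature was 2.81 (2.55 to 3.07) on the log2 scale in the upper and 3.82 (3.58 to 4.07) in the lower class.

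Most Treg-sorted cells had no Foxp3 UMI at 1000 UMIs, 550 of 738. If these were conventional cells, their other signature genes would lie near Tconv; they lay 76.9% (73.4 to 80.5) of the way from Tconv to Treg cells with a Foxp3 UMI, which argues against conventional cells as the whole of them but leaves a part open. Limited capture was not decided: the share without a UMI exceeded a Poisson draw by 6.47 points (3.16 to 9.58), between the preset bounds. It differed by -0.352 points (-3.66 to 2.76) from a draw with UMIs clumped as in the library, but the Fano factor used, 1.73, was near that of Foxp3 itself, 1.67, and holds real differences between cells, so this does not tell capture from cells low in Foxp3. Of Treg cells 12.7% had no signature UMI, against 75.3% of Tconv cells. Draws at the Treg mean of the signature gave 0.896% (Poisson) and 2.89% (UMIs clumped as in the library). Cells without a signature UMI were thus more frequent than in either draw. The clumped draw took the median Fano factor of single genes, 1.73, and not that of the summed signature. Stronger clumping of the sum would give a larger share. Whether these cells reflect such clumping, other cells in the sort or Treg cells low in the signature stays open.

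For the higher effector list in Treg, contaminating cells of other types were argued against, since without them the median was 1.09 (0.77 to 1.24), not lower than the main 0.87. Ccl5 and Nkg7 stand both in the effector list and in the CD8 or NK list of that filter, so for these genes a change is partly built in. For depth as the whole cause, the prediction was a median under 0.43 in cells thinned to the same number of UMIs. There it was 0.75 (0.50 to 1.14). Thinning draws UMIs at random and keeps the expected share of each gene within a cell. It also leaves the difference in mapped reads per UMI in place, 31.9 in Treg and 19.1 in Tconv. The thinned median could therefore not decide on depth, which stays open. The upper class held 31.7% of Treg and 15.9% of Tconv cells, a ratio of 1.999. The class is defined by the same list, so this follows from any rise of the list. It does not tell more effector-rich cells from a rise in every cell. By cluster, the list was higher in Treg by 1.29-fold in cluster 0, 1.36-fold in 1, 1.10-fold (0.955 to 1.27) in 2 and 1.80-fold in 3. Cluster 3 held 15.2% of Treg and 4.17% of Tconv cells. Genes of the list could define the clusters, so these values do not decide it either. Whether the difference belongs to Treg cells or to these mice was not tested.

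Cxcr6 had 0 UMIs in Treg and 61 in Tconv, and Klrd1, a receptor of natural killer cells, 3 and 39. Innate-like T cells in the Tconv sort are a candidate source of Cxcr6: the 25 cells with a Cxcr6 UMI carried the innate-like list at 17.5-fold (14.4 to 21.3) the level of the other Tconv cells, with Id2, Ctsw and Ccl5 most abundant, and 20.5-fold without Id2. Only 30 of the 61 UMIs lay in cells without markers of other types, whose CD8 or NK list shares Ccl5, Nkg7, Klrk1, Klrd1 and Klrb1c with the innate-like list, and the 2 richest cells held 22.9% (13.2 to 35.5) of the Cxcr6 UMIs, which argues against these 2 as the main source. The gate kept TCR beta and CD4 positive cells, which would not remove NKT cells that express CD4. Over the whole libraries the innate-like list stood at 554 CPM in Treg and 251.7 in Tconv. Without Il2rb, which is 18.5-fold higher in Treg, the list was 1.56-fold (1.33 to 1.84) higher in Tconv, at 147.1 CPM in Treg and 229.7 in Tconv. Id2 alone made up 49.04 CPM of this in Treg and 130.3 in Tconv, which is most of that excess. The whole-library ratio without both genes was not computed. The 1.56-fold value therefore does not show that innate-like genes as a group were higher in Tconv. For Klrd1 the ratio was 1.42 (0.79 to 2.37), below the 3-fold set for innate-like cells as its source, and 1 cell held both genes; its source stays unknown.

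The median Fano factor was higher in Treg than in Tconv also among cells within the pooled interquartile range of mapped reads, at 1.77 in Treg and 1.33 in Tconv, although mapped reads were not matched there, with medians of 43684 and 35679. At a resolution of 0.3 a deep cluster of 45 cells was led by Penk, Cdca7, Acot7 and Mcm5. These genes were also among the leading 10 of a cluster at a resolution of 1.0, with cells of at least 1000 UMIs and with scaled genes, where Jchain came first.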
